A study of Mus musculus with 5 samples.

How the data were processed

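RNA was sequenced from 5 samples of C2C12 cells, an established line of mouse myoblasts, the precursor cells of skeletal muscle fibres. The labels give 3 samples transfected with an empty control vector and 2 samples called miR-16 knockdown, each taken at 5 hours. Replicate numbers were read from the sample titles. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

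The deposited value table holds a normalized signal per gene, which is a read count divided by 1 size factor per sample, judged from the table's values. Low values were checked against whole multiples of 1 read. Between 88.3% and 89.1% of the values of up to 100 reads per sample came out whole within a tolerance of 0.02 reads. The remainder were fractional, so whole reads were not recovered and no count model was fitted. The table lists 12615 genes, and no gene of the mitochondrial genome is among them. Per the submitters' processing notes, the authors used STAR, Partek and DESeq2 1.34.0 with the mouse build mm9. The role of each tool, the library preparation, the strand setting and the annotation are not given in the sources used here. Without the strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart. Positions in the file differ from those of the GRCm38 annotation by a median of 133 kb, and only 354 of 12607 genes had an end within 100 bp of it. The build of the positions is therefore not settled, and chromosomes alone are given.

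A second kind of table holds the authors' own comparison, with a p-value, an adjusted p-value and a linear ratio of inhibition to control per gene, per the file headers. These deposited p-values and ratios were copied, not recomputed. The group means in it are a signal on the same size-factor scale, also the authors' own.

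Estimated depth, from the total signal and the value of 1 read, was 15.5, 20.1 and 15.4 M reads for empty vector samples 1, 2 and 3. It was 15.2 and 17 M reads for knockdown samples 1 and 2. These totals cover the listed genes only. Each of the 10 pairs of samples differed by more than counting noise, with a median chi-square per gene of 1.64 to 3.76 against 0.455 for counting noise, so every sample was counted once. The file's column names put empty vector samples 1 and 3 on 1 flow cell (A) and the other 3 samples on another (B). The lane and the number series of an identifier in these names split the samples along the same line. Flow cell stands for all of these below, since they cannot be told apart. Comparisons on flow cell B, with empty vector 2 as the only control, are given beside pooled ones.

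The design foresaw a count test for counts and a limma fit for normalized values, and the latter applied. Values were taken as log2(value + 1), on which a fold change of a low gene is understated. The 11990 genes with a mean of at least 10 over the 5 samples were tested with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and robust estimation. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Before the data were examined, 36 gene lists were fixed, and the 27 lists with at least 5 tested members were compared with all other genes by camera, with a preset correlation between genes of 0.01. The other 9 lists had too few members. They are the host genes, the mitochondrial genome with 0 members, and 7 lists of markers of other cell types.

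Genes are named by a rule set before the data were examined. It takes the host genes Dleu2 and Smc4 and any hairpin of miR-15 or miR-16, then the 10 genes per direction with the largest change among those past the threshold. Where fewer pass, it takes the smallest unadjusted p among genes with a mean of at least 50, an official symbol and no overlap between the groups. It adds the 4 members with the smallest p of each list past the threshold, and 10 fixed genes of the cell cycle, survival and muscle. For 1 gene taken by this rule the result is not reported here. Any other gene in the text was chosen after its values were seen.

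Transcript lengths and 3' UTR sequences came from GENCODE release M21, in which 98.9% of the gene symbols were found (12303 directly and 174 through older names). Each gene's longest 3' UTR was searched for the site of miR-16-5p, TGCTGCT, with an A after it (8mer) or without (7mer-m8), or GCTGCTA (7mer-A1). A further comparison was made within 10 bins of UTR length by 5 bins of expression, with 10000 permutations of the site labels inside bins. The 5 site classes, with any site and 2 or more sites as the further ones, were adjusted together, a step added after the unadjusted values were seen. The 7-base site was also ranked among 15688 words of 7 bases present in and absent from at least 100 genes each. That ranking used log2 differences with trends on UTR length, transcript length, expression and UTR base composition removed.

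The gene test was tried on simulated data of 11990 genes with 200 changed genes, drawn 20 times with independent errors. It recovered 83.2% of the changes of 2-fold and 65.6% of those of 1.5-fold, with 14.7 false calls per simulation. A list of 40 genes moved by 0.3 (log2) was found in 100% of the simulations, and 0.185% of the lists left unmoved were called. Simulated genes varied independently of each other, so this rate does not carry over to lists whose genes move together. In the data the estimated correlation within a tested list ran from -0.0733 (nuclear retained RNA) to 0.524 (miRNA pathway). In 10 simulations of 11517 genes, with log2 differences shuffled over genes, a shift of 0.1 given to genes with an 8mer was estimated at 0.101 within bins. Shuffling removed any tie with UTR length and expression, and the shift is larger than those found below. The simulation therefore does not show how well the bins remove such ties.

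Alternatives fixed before the data were examined were a fit without the trend, one without robust estimation, quantile normalization, pseudocounts of 0.5 and 5, no filter, a filter at a mean of 50, each sample left out, and the replicate number as a block. For lists they also covered an estimated correlation and fry, and for site genes other site classes and matching. Only empty vector 3 carries its replicate number, so the block gives the same log2 differences as the fit without empty vector 3. Chosen after seeing the data were a flow cell term, also together with an estimated correlation, flow cell B alone, removal of each sample's trend with transcript length by a spline with 4 degrees of freedom, readjustment of the authors' p-values, and, for site genes, an estimated correlation and matching on transcript length as well. Tables that repeat parts of the authors' comparison were not used here. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the tables, and matplotlib 3.10.9 drew the figures.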

Results

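The transcriptome of C2C12 myoblasts was measured by RNA sequencing 5 hours after transfection with a plasmid. MicroRNA miR-16 binds short sites in the 3' UTRs of messenger RNAs and lowers their level or translation, and the series asks what the muscle precursor cell expresses when it is reduced. There were 3 empty vector samples and 2 miR-16 knockdown samples, at an estimated 15.2 to 20.1 M reads each. The labels call the group a knockdown, whereas the treatment protocol speaks of plasmid DNA for miR-16-1. The mature miRNA was not measured in these tables, so the direction of the manipulation rests on the group label.

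For the genes that carry the miR-16 hairpins, no difference between the groups was detected. Dleu2, the long non-coding host of miR-15a and miR-16-1 on chromosome 14, had normalized counts of 16.02, 23.5 and 11.8 in the empty vector samples and 12.9 and 21.6 in the knockdown samples. Smc4, the condensin subunit gene that hosts miR-15b and miR-16-2 on chromosome 3, stood at 5386 ± 461 (SD, n = 3) and 5142 ± 51.0 (SD, n = 2). The limma log2 differences, knockdown minus empty vector, were 0.022 with a standard error of 0.50 (adjusted p = 0.993) and -0.063 with a standard error of 0.082 (adjusted p = 0.858). On flow cell B alone the log2 differences were -0.47 for Dleu2 and 0.083 for Smc4. The hairpins themselves were not analysed here, and the level of a host transcript need not follow that of a miRNA blocked after transcription.

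No single gene passed the threshold between knockdown and empty vector. Of the genes named by the fixed rule, 5 are described first. H19, an imprinted non-coding RNA abundant in embryonic muscle, had 313 ± 108 normalized counts (SD, n = 2) with knockdown and 133 ± 39.2 (SD, n = 3) with empty vector, a ratio of 2.34. Igf2, the imprinted growth factor gene beside it on chromosome 7, had 43.9 ± 4.20 (SD, n = 2) and 21.3 ± 8.39 (SD, n = 3). Ccne1, which encodes the cyclin E1 of the G1/S transition, had 858 ± 30.7 (SD, n = 2) and 675 ± 51.5 (SD, n = 3). Lower values with knockdown included Helz2, a helicase coactivator gene, at 474 ± 65.0 (SD, n = 2) against 725 ± 66.5 (SD, n = 3), and Ago3, which encodes an Argonaute protein, at 228 ± 95.4 (SD, n = 2) against 411 ± 13.6 (SD, n = 3).

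The limma log2 differences were 1.22 ± 0.26 (SE) for H19, 1.09 ± 0.43 for Igf2, 0.35 ± 0.10 for Ccne1, -0.62 ± 0.12 for Helz2 and -0.91 ± 0.21 for Ago3. Their adjusted p-values were 0.527, 0.565, 0.535, 0.527 and 0.527, so none of the 5 passed. Their groups did not overlap, which was a condition for naming H19 and Helz2 and held for 23.8% of all tested genes. Against empty vector 2 alone, on the same flow cell, the log2 differences were 1.25, 0.65, 0.46, -0.56 and -0.89.

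Further genes with the smallest p had higher values with knockdown. Rplp1 and Rpl35 of the ribosome had log2 differences of 0.32 and 0.36, Myl6, a non-muscle myosin light chain gene, 0.40, and the galectin gene Lgals1 0.27. Selp, which encodes P-selectin, had 0.32, S100a13 0.59, Ubxn6 0.43, Rpl22l1 0.63 and Spryd3 0.33. On the lower side, Vps13a, a lipid transfer protein gene, had a log2 difference of -0.53, the transporter genes Abca2 and Slc5a3 -0.49 and -0.46, and Zfp292 -0.50. Xist had -0.48, Aff4 -0.40, Ahnak2 -0.39 and Bmpr2, a BMP receptor gene, -0.41. None of these genes passed the threshold (adjusted p of 0.527 to 0.535). Without knockdown 2, Xist had -0.28. With the trend on transcript length removed, Xist had -0.15, Bmpr2 -0.16, Aff4 -0.20, Slc5a3 -0.24, Zfp292 -0.30, Vps13a -0.31, Rplp1 0.15 and Lgals1 0.14. On flow cell B alone, Myl6 had 0.18, Rpl35 0.22, S100a13 0.31, Rpl22l1 0.28, Zfp292 -0.32 and Bmpr2 -0.24.

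By limma, 0 of 11990 genes passed, and the lowest adjusted p was 0.527. At an unadjusted p under 0.05 there were 975 genes, 339 higher and 636 lower with knockdown, where chance would give 600. Of these, 12% differed by at least 1.5-fold. Without the variance trend, limma also called 0 genes, with 697 at an unadjusted p under 0.05. The groups did not overlap for 2855 genes, or 23.8%, against 20% by chance. Single libraries decided the count, since 28 genes passed without empty vector 2 (24 higher, 4 lower) and 107 without knockdown 1 (1 higher, 106 lower).

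**Figure D1:**
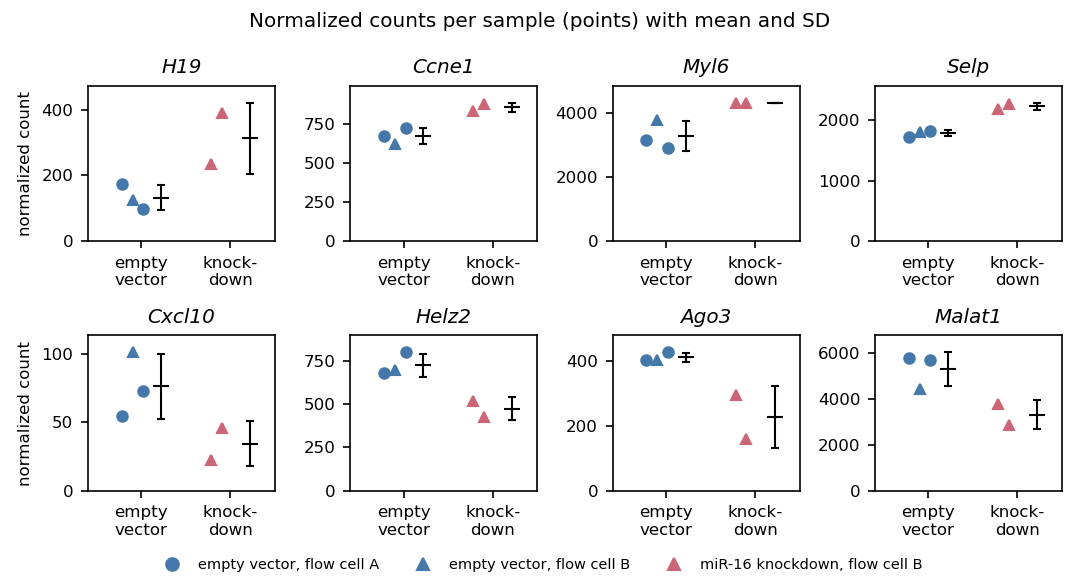
Normalized counts (y axes, linear from 0) of 8 named genes in each sample, by group, with circles for flow cell A and triangles for flow cell B, and the group mean with its SD beside the points. In all 8 genes the 2 knockdown samples lie outside the range of the 3 empty vector samples, for example at 236 and 389 for H19 against 97.5 to 175, while no gene passed the threshold. This follows largely from the choice of genes. H19, Myl6, Selp and Helz2 were taken on the condition of no overlap, and the others had small p-values within their lists.

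Genes of the interferon response fell with knockdown as a group. Of 40 measured members, 35 had lower values, with a median log2 difference of -0.29 (camera adjusted p = 6.22e-06, or adjusted p = 0.561 with an estimated correlation). Cxcl10, a chemokine gene induced by interferon, had 34.3 ± 16.5 normalized counts (SD, n = 2) with knockdown and 76.2 ± 23.7 (SD, n = 3) with empty vector. Ddx58, which encodes the RNA sensor RIG-I, had 224 ± 12.8 (SD, n = 2) and 329 ± 40.6 (SD, n = 3), while Parp14 and the GTPase gene Igtp had log2 differences of -1.35 and -2.41 at low counts. Parp14 had 32.35 and 15.01 in knockdown samples 1 and 2, against 39.51, 93.32 and 52.5 in the empty vector samples. The list of NF-kB targets and chemokines fell as well, with 14 of 16 members lower and a median of -0.28 (camera adjusted p = 1.33e-04, or adjusted p = 0.477 with an estimated correlation). In it, Ccl7 and Ccl2, which encode monocyte attractants, had log2 differences of -0.67 and -0.58, and Tnfaip3, an inhibitor of NF-kB signalling, -0.44.

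No interferon gene passed when adjusted over the list alone, whereas Ccl7, Cxcl10 and Ccl2 passed when the NF-kB list was adjusted over the list alone, and 0 members of either passed over all genes. On flow cell B the medians were -0.50 and -0.39. The mean of the interferon list lay at -0.264, 0.286 and -0.023 in empty vector samples 1, 2 and 3 relative to their mean, and at -0.439 and -0.318 in knockdown samples 1 and 2. Without empty vector 2, the control with the highest mean, the interferon median was -0.16 (adjusted p = 0.0183), and with a filter at a mean of 50 it was -0.18.

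Cell cycle genes moved in both directions. G1/S genes rose slightly, with 28 of 34 members higher and a median log2 difference of 0.050 (camera adjusted p = 0.00711, or adjusted p = 0.561 with an estimated correlation). Besides Ccne1, its named members Gins2, Rrm2 and Tk1, which serve DNA replication and nucleotide supply, had log2 differences of 0.36, 0.17 and 0.21, and none passed when adjusted over the list alone. Genes of cell cycle inhibitors and the p53 response fell, with 15 of 22 members lower and a median of -0.098 (camera adjusted p = 0.0485, or adjusted p = 0.561 with an estimated correlation). Eda2r, Mdm2, Ccng1 and Trp53inp1, all known p53 targets, had log2 differences of -0.43, -0.33, -0.25 and -0.44 and were the 4 members that passed when adjusted over the list alone. Cdkn2c, an inhibitor of CDK4 and CDK6 chosen after its values were seen, had 0.28 in the opposite direction. On flow cell B the medians were 0.093 and -0.21.

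Both cell cycle calls were lost under several alternatives. The G1/S list gave an adjusted p of 0.113 without empty vector 2 and 0.0795 without knockdown 2. The p53 list gave 0.538 without empty vector 2 (median -0.065) and 0.38 without knockdown 1 (median -0.17), while its median was -0.17 without empty vector 3 and -0.18 with a filter at a mean of 50. With all samples kept, the p53 list gave an adjusted p of 0.059 with quantile normalization and 0.0566 with no filter on low values. The mean of the p53 list was lower in empty vector 3, at -0.15, than in knockdown samples 1 and 2, at -0.096 and -0.037.

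Genes of the ribosome, oxidative phosphorylation, the proteasome and glycolysis rose when all 3 controls were pooled, in 4 lists. The calls were lost for each list with an estimated correlation (adjusted p = 0.561 for ribosomal proteins, 0.561 for oxidative phosphorylation, 0.742 for the proteasome and 0.761 for glycolysis). Of 60 cytosolic ribosomal protein genes, 58 had higher values, with a median log2 difference of 0.17, and Rpl27 and Rps12 stood at 0.35 and 0.41. Nuclear-coded subunits of oxidative phosphorylation rose by a median of 0.13, with 43 of 47 higher, among them Ndufa1 at 0.83, Cox5a at 0.25, Uqcrfs1 at 0.24 and Ndufb6 at 0.38. Proteasome genes had a median of 0.078 with 25 of 31 higher, including Psmb6 at 0.27, Psma6 at 0.21, Psmb7 at 0.22 and Psmc1 at 0.16. Glycolysis genes had a median of 0.076 with 14 of 21 higher, including Pgk1 at 0.25, Eno3 at 0.17, Ldha at 0.13 and Tpi1 at 0.14.

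Against empty vector 2 on the same flow cell, these 4 medians were 0.024, 0.026, 0.0037 and -0.031, and with a flow cell term none passed (adjusted p of 0.274, 0.0927, 0.294 and 0.889). The pooled camera adjusted p-values were 4.76e-17, 2.45e-09, 7.88e-04 and 0.0485. Only Rplp1 and Rpl35 passed when adjusted over the list alone, and no member of the other 3 lists did. Without empty vector 2 the medians of the ribosomal and glycolysis lists were 0.265 and 0.133. The proteasome list gave a median of 0.051 and an adjusted p of 0.0774 without knockdown 2. The glycolysis list gave adjusted p-values of 0.329, 0.0924 and 0.443 without empty vector 1, empty vector 3 and knockdown 2, with medians of 0.054, 0.041 and 0.048. With all samples kept, its adjusted p was 0.13 without the variance trend, 0.124 with quantile normalization and 0.0769 with no filter, and 11 of 17 alternatives ended or turned its call.

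Genes of the miRNA pathway itself fell as a list, with 10 of 12 members lower and a median log2 difference of -0.15 (camera adjusted p = 0.00389, or adjusted p = 0.742 with an estimated correlation). The list rested on knockdown 2, without which its median was -0.042 (adjusted p = 0.589). Ago3 had -0.91, Tnrc6b -0.34 and Dicer1 -0.22, while Tarbp2, which encodes a partner of Dicer, had 0.31. Without knockdown 2, Ago3 had -0.47 and Tnrc6b -0.14, and without knockdown 1 they had -1.35 and -0.55. With the trend on transcript length removed, Ago3 had -0.61, Tnrc6b -0.018 and Dicer1 -0.019. Growth signalling genes fell by a median of -0.098, with 24 of 32 lower (camera adjusted p = 0.012, or adjusted p = 0.477 with an estimated correlation). Among them Igfbp3, an IGF binding protein gene, had -0.30, Rptor of the mTOR complex -0.26 and Irs1, the insulin receptor substrate, -0.27, with Igf2 in the opposite direction. With the trend on transcript length removed, Igfbp3 had -0.33, Rptor -0.15 and Irs1 -0.085. In knockdown samples 1 and 2, Rptor had 2109 and 1681 normalized counts and Irs1 3447 and 2742. The nuclear retained RNA list, fixed as a measure of library quality, fell by a median of -0.48, with 5 of 7 members lower (camera adjusted p = 0.00306, or adjusted p = 0.477 with an estimated correlation). Its median was -0.12 with a filter at a mean of 50 and -0.20 with the trend on length removed. Malat1 had -0.68, Kcnq1ot1 -1.35 and Rn7sk -0.85, the last with 0.46 on flow cell B. With the trend on length removed, Malat1 had -0.55, Kcnq1ot1 -0.576 and Rn7sk -1.055. Kcnq1ot1 had 5.39 and 19.7 normalized counts in knockdown samples 1 and 2, against 39.5, 23.5 and 24.6 in the empty vector samples.

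On flow cell B the medians of these 3 lists were -0.13, -0.086 and -0.29. Adjusted over the list alone, Ago3, Tarbp2 and Tnrc6b passed in the miRNA list, Xist and Malat1 in the nuclear list, and none in the growth list. The mean of the miRNA list was -0.316 in knockdown 2 and 0.0081 in knockdown 1, and without knockdown 1 its median was -0.25. Without knockdown 2 the growth list had -0.036 (adjusted p = 0.0774) and the nuclear list -0.28.

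**Figure D2:**
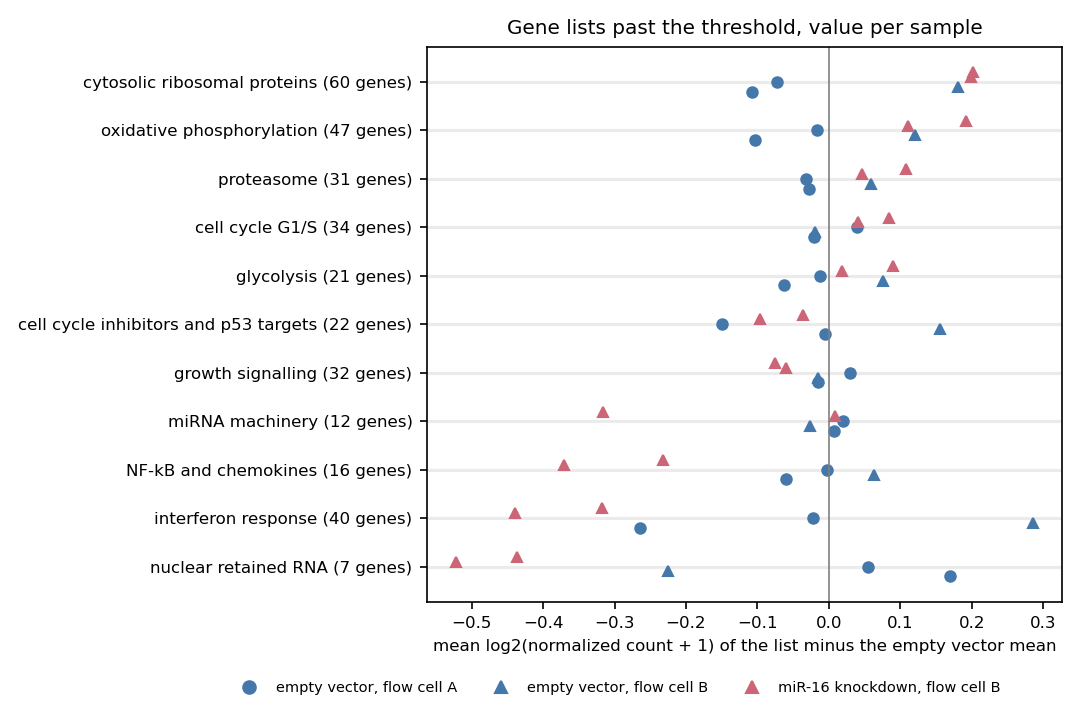
Mean log2(normalized count + 1) of each of the 11 gene lists past the threshold, per sample, relative to the mean of the empty vector samples (x axis), with circles for flow cell A and triangles for flow cell B. Empty vector 2 lies with the knockdown samples for ribosomal proteins, at 0.181 against 0.199 and 0.202, and apart from them for the interferon list, at 0.286 against -0.439 and -0.318.

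Transcript length followed the comparison across all genes. The shortest of 10 groups of transcripts, with a median of 985 nt, had a median log2 difference of 0.14, and the longest, with a median of 8206 nt, had -0.18. The slope was -0.089 per doubling of length against all controls and -0.036 against empty vector 2 alone. Per sample it was 0.035, -0.053 and 0.018 in empty vector samples 1, 2 and 3 and -0.050 and -0.129 in knockdown samples 1 and 2. With these trends removed, the median of the ribosomal list was 0.063 (adjusted p = 1.43e-04) and that of the interferon list -0.30 (adjusted p = 1.48e-10). The lists of oxidative phosphorylation (0.057), proteasome (0.016), glycolysis (0.046), miRNA pathway (-0.019) and growth signalling (0.0017) no longer passed, with adjusted p-values of 0.0617, 0.929, 0.14, 0.675 and 0.675.

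Ribosomal RNA split along the line of the flow cells, which is also that of the lane and the identifier series, and Rn45s by group as well. Rn18s, the 18S ribosomal RNA, took 1.46% and 2.94% of the signal in empty vector samples 1 and 3, 0.467% in empty vector 2, and 0.413% and 0.536% in the knockdown samples. The controls on flow cell A thus held 4.77 times the Rn18s of empty vector 2, which held 0.995 times the knockdown mean. Lars2, chosen after its values were seen like Rn18s, showed ratios of 4.45 and 0.848. Rn45s, the ribosomal RNA precursor, also chosen after its values were seen, had 50194, 35322 and 44656 normalized counts in the empty vector samples and 27222 and 30326 in the knockdown samples. Its log2 difference was -0.58 by limma (adjusted p = 0.535) and -0.30 on flow cell B.

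**Figure D3:**
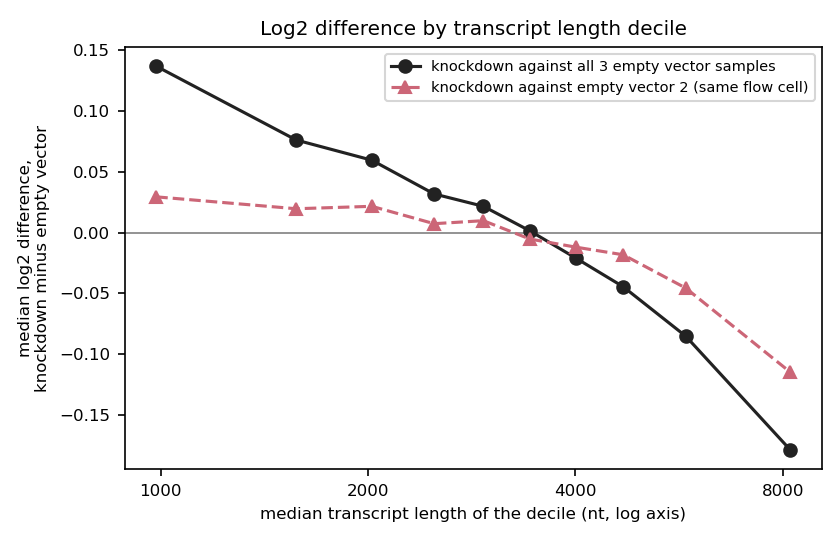
Median log2 difference, knockdown minus empty vector (y axis), of genes in 10 groups of transcript length (x axis, nt, log scale), against all 3 controls and against empty vector 2 alone. The line for all controls runs from 0.137 to -0.179 and the line for empty vector 2 from 0.0294 to -0.115.

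In the muscle identity genes tested, no difference was detected. Myod1, the master regulator of the myoblast, stood at 1577 ± 31.8 (SD, n = 2) with knockdown and 1613 ± 74.7 (SD, n = 3) with empty vector, and Myog was not analysed here. The lists of myogenic regulators and sarcomere genes gave camera adjusted p-values of 0.793 and 0.585. They cover part of their lists, with 19 of 29 and 13 of 40 fixed members tested. Genes often named as miR-16 targets went both ways. Besides Ccne1, Ccnd3 and Wee1 had log2 differences of 0.21 and 0.20, Ccnd1 0.014, Bcl2 0.097, Ccnd2 -0.12 and Cdk6 -0.15, none past the threshold (adjusted p of 0.535 to 0.971). On flow cell B, Wee1 had 0.42, Ccnd3 0.095 and Cdk6 0.096. Wee1 had 722 normalized counts in empty vector 2, against 908 and 899 in empty vector samples 1 and 3. Mki67, a marker of proliferation with a long transcript, had -0.38 (adjusted p = 0.577). It had -0.18 with the trend on transcript length removed and -0.20 on flow cell B. Its normalized counts in knockdown samples 1 and 2 were 11846 and 8414. Of the 47 measured members of the fixed list of miR-16 targets, 23 were higher and 24 lower (adjusted p = 0.955).

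The 16 other lists tested gave adjusted p-values from 0.119 to 0.959. Besides those named, they cover G2/M (0.119), muscle protein breakdown (0.959), mitochondrial biogenesis (0.955), hypoxia (0.585), immediate early genes (0.625), unfolded protein and amino acid stress (0.133), heat shock (0.7), oxidative stress (0.682), cholesterol synthesis (0.439), extracellular matrix (0.565), TGF-beta targets (0.826), apoptosis (0.7) and histones (0.637). Adjusted over the list alone, 1 gene of these lists passed, the hypoxia gene Ndrg1. Of the markers of other cell types, each list had 1 to 4 measured members, too few for the list test. Their median log2 differences were -0.010 for fibroblast, 0.071 for adipocyte, 0.44 for macrophage, -0.32 for endothelial, 0.036 for osteoblast, -0.11 for neural and -0.28 for red cell markers. The macrophage value came from Cd68 at 0.88, with Cd14 at 0.0013, and Cd68 passed when adjusted over the list alone.

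Genes with a miR-16 site in the 3' UTR had slightly lower values than genes without one in the knockdown samples, but not once genes of similar UTR length and expression were compared. The 548 genes with an 8mer had a median log2 difference of -0.022 and the 8149 genes without a site 0.0085. Their gap was -0.030, as it was for 2409 genes with the 7mer-m8 site, and it was -0.021 for 411 genes with the 7mer-A1 site and -0.029 for all 3368 genes with a site. By camera with Benjamini-Hochberg adjustment over 5 overlapping classes, these gave adjusted p = 0.086, adjusted p = 0.0939, adjusted p = 0.217 and adjusted p = 0.0939. Only the 1080 genes with 2 or more sites passed, with a gap of -0.043 and an adjusted p = 0.0272, and they did not with an estimated correlation. Without knockdown 2 the gaps were -0.0070 for the 8mer, -0.010 for the 7mer-m8, -0.0032 for the 7mer-A1, -0.0084 for any site and -0.013 for 2 or more sites. Without knockdown 1 they were -0.067, -0.049, -0.047, -0.051 and -0.074.

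Within bins of UTR length and expression the sign turned. The values there are weighted differences of means, whereas the gaps above are differences of medians, so matching is not the only change. The difference was 0.012 for the 8mer (permutation p = 0.22), 0.018 for the 7mer-m8 (permutation p = 0.0015), 0.026 for the 7mer-A1 (permutation p = 0.031), 0.018 for any site (permutation p = 6e-04) and 0.017 for 2 or more sites (permutation p = 0.024). Adjusted over the 5 classes by Benjamini-Hochberg, these permutation values were 0.22, 0.00375, 0.0387, 0.003 and 0.0387. On flow cell B the differences were 0.019, 0.013, 0.021, 0.015 and 0.0041, and after adjustment none of the classes passed (permutation p of 0.2, 0.115, 0.2, 0.06 and 0.65). Without knockdown 1, in the same order of classes, the differences were 0.0013, 0.014, 0.015, 0.012 and 0.014, each smaller than the pooled one. Without empty vector 3 they were 0.011, 0.013, 0.023, 0.014 and 0.0091. The unadjusted permutation p-values were 0.34, 0.03, 0.075, 0.011 and 0.27, each higher than its pooled value before adjustment. With the replicate block, whose log2 differences per gene are those without empty vector 3, they were 0.32, 0.029, 0.073, 0.013 and 0.26, also unadjusted. Without knockdown 2 the differences were 0.022, 0.021, 0.037, 0.024 and 0.020. The fits without knockdown 1 and without knockdown 2 each keep 1 knockdown sample. Matched on transcript length as well, a step chosen after the data were seen, the pooled differences were 0.0183, 0.0196, 0.0286, 0.0205 and 0.0209. Their unadjusted permutation p-values were 0.059, 8e-04, 0.016, 2e-04 and 0.0046. On flow cell B the differences so matched were 0.024, 0.0149, 0.0226, 0.0173 and 0.00748. The permutations treat genes as independent, which they are not. They also keep the samples fixed, so their p-values do not measure variation between samples. For any site, other splits of the 5 samples into 3 and 2 gave differences within bins from -0.0158 to 0.0117, against 0.0178 for the real split. These splits were also chosen after the data were seen, and 10 splits are too few for a share under 0.05.

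The authors' deposited table called 70 genes at an adjusted p under 0.05, 13 higher and 57 lower with inhibition. In the authors' deposited table, Rplp1, Lgals1, Myl6 and Selp had ratios of 1.25, 1.21, 1.31 and 1.25, and Slc5a3, Xist, Abca2 and Malat1 had 0.725, 0.721, 0.709 and 0.626. All 70 genes had the same sign in the limma fit, an unadjusted p under 0.05 there, and the same sign against empty vector 2 alone. Both tests used the same 5 samples, so this is no separate support. Not every gene with a small limma p was matched. Helz2 had an unadjusted p of 1.05e-04 by limma and 0.249 in the authors' deposited table. Of the interferon list, 0 genes were among the 70. Its members Ddx58, Cxcl10, Parp14 and Igtp had unadjusted p-values of 0.38, 0.2, 0.162 and 0.0474 in the authors' deposited table. The median transcript length was 800 nt for the genes called higher and 10042.5 nt for those called lower, against 3174.5 nt for all tested genes. With the trend on length removed, 53 of the 70 kept an unadjusted p under 0.05. Across 11456 genes in both tables, which are not independent replicates, log2 ratios of the authors' deposited table correlated with the limma differences at r = 0.985 and rho = 0.993. The authors' deposited table gives no adjusted p for 42.7% of its genes, among them H19, whose unadjusted p there was 3.05e-07 and whose ratio was 2.36.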

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

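Tests with a flow cell term (also with an estimated correlation), on flow cell B alone or with length removed, the readjusted authors' p-values, and for site genes the estimated correlation and matching on transcript length, were chosen only after the result was seen. Over 17 alternatives for each of the 11 lists, 154 values kept direction and call, 30 lost the call and 3 turned, and 3 lists were kept under every alternative with the preset correlation. These alternatives are not all separate checks. The list test does not use robust estimation, so leaving that out repeats the main values. A flow cell term and flow cell B alone gave the same medians, and so did the block and the fit without empty vector 3. With an estimated correlation 0 lists passed, also with a flow cell term (0), and by fry 0. Growth signalling turned to 0.0017 with length removed, and glycolysis to -0.031 with a flow cell term and on flow cell B. The block also ended the glycolysis call (0.041). Of 68 named genes, 10 changed sign somewhere and 37 passed the threshold in some alternative. With the replicate block, which leaves 1 residual degree of freedom, 36 passed, against 5 without empty vector 2. Leaving out 1 sample gave 0 to 107 genes past the threshold. The samples share only a number, with correlations of same-numbered deviations of 0.0864 and 0.0286, and the replicate block gave 311 genes, or 62 with length removed as well. With the block, Dleu2 had -0.20, Bcl2 -0.068 and Myod1 5.04e-05. With a flow cell term, and equally on flow cell B, Dleu2 had -0.47, Smc4 0.083, Psmb7 -0.013, Psmc1 -0.032, Rn7sk 0.46, Cdk6 0.096, Bcl2 -0.028 and Myod1 0.038. With length removed Cdk6 had 0.081, and with the block too, Dleu2 had -0.18, Smc4 0.0064, Tnrc6b 0.040, Dicer1 0.0049 and Cdk6 0.14. Quantile normalization gave Ccnd1 -0.00448. With 1 sample left out, Dleu2 ranged from -0.33 to 0.37, Ccnd1 from -0.046 to 0.073, Ccnd2 from -0.27 to 0.026, Bcl2 from -0.0948 to 0.29 and Myod1 from -0.067 to 5.04e-05. For 8mer genes, at an unadjusted threshold, the difference was -0.030 without the variance trend and with an estimated correlation, -0.019 with the block and -0.0049 with a flow cell term and on flow cell B, all short of the threshold, and it ranged from -0.067 to -0.0070 with 1 sample left out. It turned to 0.031 with length removed, 0.038 with the block too, 0.012 matched on UTR length and expression and 0.018 matched on transcript length as well. The matched values are differences of means, and the unmatched ones are differences of medians. Other classes gave -0.030 (7mer-m8), -0.021 (7mer-A1) and -0.029 (any site). The authors' deposited table called 4 genes at 0.01, 143 at 0.1 and 38 with all its p-values readjusted. The cause of these changes was not tested.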

Other observations

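The tests of the length and interferon patterns, the count of splits for the site word, and all values with a flow cell term or with length removed were chosen only after the result was seen. Genes of the G2/M phase, which serve chromosome segregation and mitosis, stood higher with knockdown on flow cell B, where 32 of 37 members were higher with a median log2 difference of 0.11 (camera adjusted p = 7.22e-06 with a flow cell term, or adjusted p = 0.383 with an estimated correlation in the same fit). Pooled over all controls, 26 were higher and the median was 0.041 (camera adjusted p = 0.119, or adjusted p = 0.761 with an estimated correlation). Also past the threshold with a flow cell term but not when pooled, on the lower side, were immediate early genes (18 of 25 lower, median -0.087), unfolded protein and amino acid stress (22 of 28, median -0.093) and oxidative stress (13 of 21, median -0.067), each at a camera adjusted p of 0.0461. With an estimated correlation in the same fit these 3 gave adjusted p = 0.771, 0.771 and 0.452. Pooled calls appeared without empty vector 3 for G2/M, immediate early genes and unfolded protein stress (camera adjusted p of 0.00583, 0.00679 and 0.0208). With the replicate block the same lists and TGF-beta targets passed (camera adjusted p of 0.0188, 0.00834, 0.0262 and 0.0366). The median of TGF-beta targets was then -0.126, as it was without empty vector 3, against 0.042 pooled. The block gives the log2 differences of the fit without empty vector 3, so it is no separate check. Without knockdown 2 the medians of unfolded protein stress and cholesterol synthesis were -0.082 and 0.085, against -0.038 and 0.020 pooled. With length removed, G2/M, unfolded protein stress and oxidative stress passed (camera adjusted p of 0.0281, 1.5e-04 and 0.0213). Flow cell B holds 1 control, so the values on it rest on empty vector 2. The G2/M list mean was 0.009, -0.065 and 0.056 in empty vector samples 1, 2 and 3. In knockdown samples 1 and 2 it was 0.038 and 0.006, within the control range. Empty vector 3 lay below both knockdown samples for immediate early genes (-0.125 against -0.029 and -0.053) and oxidative stress (-0.060 against -0.027 and -0.047). For unfolded protein stress it lay at -0.055, between -0.092 and -0.040.

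Short transcripts lay higher and long ones lower with knockdown. Against empty vector 2 alone the slope was -0.0363 per doubling of length, and -0.0893 against all controls. That comparison has 1 control, so it leaves open whether the flow cell accounts for part of the trend. With each sample's trend removed, the ribosomal protein list kept a median of 0.0628 (adjusted p = 1.43e-04), which leaves open whether uneven capture of length in single libraries accounts for its whole rise. An effect of the knockdown on long transcripts was not tested apart from these.

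Genes with a miR-16 site differed from genes without one, and the sign depended on the comparison. The lower value of 8mer genes may come from UTR length and expression, since it became 0.0123 among genes alike in both. This value is a difference of means, whereas the unmatched gap is one of medians. It was 0.0013 without knockdown 1 and 0.022 without knockdown 2. The site TGCTGCT ranked at percentile 99.6 of all words, on the higher side, the direction that release of miR-16 targets would give. More miR-16 in the samples labelled knockdown would place it at the low end. The overlapping words GCTGCTG and CTGCTGC ranked at 96.7 and 84.3. Without knockdown 2, TGCTGCT, GCTGCTG and CTGCTGC ranked at 99.5, 96 and 98.2, and without knockdown 1 at 96.7, 90.4 and 32.5. The high rank was thus partly shared with overlapping words. Of the 10 splits of the 5 samples, 2 placed the word as far from the middle, with a z of 2.63 for the real split and an absolute value of 2.75 for the highest other. With 10 splits a share under 0.05 cannot be reached.

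Interferon genes were lower with knockdown. The list had a median transcript length of 2336 nt, against 3174.5 nt for all tested genes, and shorter transcripts lay higher with knockdown. The trend of all genes with length would thus raise this list, not lower it. The median of -0.30 with length removed is therefore no separate test, since removal could hardly shrink the fall. The flow cell stays open, since the median of -0.496 on flow cell B rests on empty vector 2, the control with the highest list mean, and was -0.16 without it. The list mean differed by 0.55 between empty vector samples, against -0.378 between the groups, so variation between samples may account for it. Of the 10 splits, 3 gave as small a camera p, the lowest of another split being 2.34e-16 against 6.91e-07 for the real one, and an effect of the knockdown itself stays open.

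Of the 10 splits, 2 gave at least as many lists past the threshold, with 11 for the real split and 12 for the highest other, too few splits for a share under 0.05. The split along the flow cells called 136 genes, which points to a structure of the samples, and 7 of the splits called 0.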
